A study of Mus musculus with 3 samples.

How the data were processed

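Single-nucleus RNA was profiled from mouse brain tumours with droplet capture and unique molecular identifiers (UMIs), which count RNA molecules rather than PCR copies. Per the labels' protocols, neural stem cells of newborn Ink4a/Arf-null, Pten-floxed mice were transduced with RCAS retroviral vectors carrying red fluorescent protein and either a scrambled hairpin or 1 of 2 hairpins against Pde10a, called shPde10a-1 and shPde10a-4 here. Red cells were sorted, and later tumours were cut out of the surrounding brain by eye, frozen and broken into nuclei that were purified on a sucrose gradient. Each library pooled the tumours of 2 mice of 1 condition, so there were 3 libraries and 1 per condition. The deposited values were whole-number UMI counts per gene and barcode, in a filtered matrix per library. Per the submitters' processing notes the tools were Cell Ranger 6.1 and Cell Ranger 7.1.0 with the mm10 genome. Which version made which library, and whether intronic reads were counted, was not given in the sources used here. If the libraries were made with different versions, levels would not be comparable between them.

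The matrices held 22060 features, of which 5 were added sequences for the vector and its cargo, among them RCAS, PDGFA and mRFP. The 2 features named for the scrambled hairpin had 0 UMIs in every library, so the counts did not check which hairpin a library carried. Gene IDs were matched to the GENCODE M21 annotation of the same build, with 22029 matches, and coordinates are 1-based. Barcodes with under 500 UMIs, under 300 genes or over 5% mitochondrial UMIs were left out, which removed 69, 190 and 259 barcodes of the scrambled, shPde10a-1 and shPde10a-4 libraries. All of them failed on mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy. Its automatic threshold marked only 0.105%, 2.34% and 0.123% of barcodes, so the planned rule was replaced, after the scores were seen, by removing the top-scoring share expected at 0.8% per 1000 barcodes. This marked 181, 168 and 258 barcodes, some of which in the hairpin libraries had failed the filters as well, and left 4512, 4228 and 5175 nuclei.

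Nuclei of all libraries were clustered together without integration, on 2000 variable genes and 30 principal components with 20 neighbours and Leiden resolution 1. This gave 34 clusters. Clusters of at least 20 nuclei were named from 18 marker sets fixed before the data were examined. A name needed at least 3 markers at 2-fold or more above the median cluster. A cluster stayed unnamed if another set had at least 2 more markers than its own among its top 10 genes, a bound loosened from 1 after the clusters were seen. Without that change the striatal projection neuron-like class, the macrophage or monocyte-like class and cluster 17 of the inhibitory neuron-like class would have stayed unnamed. It also stayed unnamed if it was shallow and had none of its own markers there. The tumour compartment was the 11 clusters named OPC-like (oligodendrocyte precursor-like) or proliferating progenitor-like. Tumour nuclei could not be told from host precursors by marker names alone, so the transgene features are given beside them.

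With 1 library per condition no test was run. UMIs were summed per library and class and given as CPM (UMIs of a gene over the sum of all UMIs of the class, scaled to a common total) with exact 95% Poisson intervals. Ratios carry exact conditional binomial intervals and shares of nuclei carry Clopper-Pearson intervals. All of these cover counting error only and compare libraries, not conditions. Log2 ratios used 0.5 UMI added to each sum. Genes of at least 20 CPM in any library were called higher or lower by a size rule of 2-fold in both hairpin libraries against scrambled. Named genes were the 12 in each direction with the largest smaller ratio, and the top 5 in each direction for shPde10a-4 against shPde10a-1 and for other classes of at least 100 nuclei in every library. Left out of that ranking were mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes, unnamed gene models, and genes over 10 times higher in another class, which free RNA can carry into tumour nuclei. Pde10a, Pten, Cdkn2a and up to 8 members per gene list, by level and by size, could also be named. The 30 gene lists were fixed before the data were examined. A list's median log2 ratio was taken over members of at least 5 CPM and placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Members were called higher or lower at 1.5-fold. Dividing nuclei had a UMI in at least 2 G2/M genes after each nucleus was thinned to 1500 UMIs.

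The size rule was tested on simulated counts for the tumour compartment with both hairpin libraries set against scrambled, over 7206 genes with 200 changed. It passed 0 of 50 genes at a true 1.5-fold difference, 17 of 50 at 2-fold, 50 of 50 at 3-fold and 50 of 50 at 4-fold, and 0 of 7006 unchanged genes. All draws were Poisson and held counting error only, so they do not measure how often unchanged genes pass between different pools of mice. Ratio intervals held the true ratio in 93.9% of 1000 draws. Among simulated lists of 15 genes without a difference, 6.67% fell outside percentiles 2.5 to 97.5, while 100% of lists with a true 1.3-fold difference lay above 97.5.

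The alternatives were 17 settings chosen before the data were examined and 5 added after, over filters, doublets, resolution, scaling, depth, thresholds and the make-up of the tumour compartment. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0, with edgeR 4.0.16 in R 4.3.3 used only for TMM scaling factors. Other choices made after values were seen were the 5 lists treated as main results (proneural, mesenchymal, hypoxia, G2/M and PI3K-AKT-mTOR), the transgene threshold of 400 CPM, the sex-linked genes, the region of chromosome 17, the genome windows and the microglia-like comparison.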

Results

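The study asked whether Pde10a, a gene on mouse chromosome 17 whose human counterpart lies on distal 6q, acts as a tumour suppressor and regulates PI3K signalling in glioblastoma. Nuclei came from tumours that arose from neural stem cells carrying a scrambled hairpin, shPde10a-1 or shPde10a-4, with 1 library per condition from 2 pooled mice. The scrambled library held 24524766 UMIs in 4762 barcodes (median 4088 UMIs per barcode), the shPde10a-1 library 20837096 in 4576 (median 3253) and the shPde10a-4 library 25987357 in 5680 (median 3477). There were no replicates, so every comparison below is between libraries and its interval covers counting error only.

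The targeted gene was only slightly lower in the tumour compartment of the hairpin libraries. Pde10a encodes a phosphodiesterase that breaks down cAMP and cGMP, and it lies on chromosome 17 from 8525372 to 8986648 in mm10 (ENSMUSG00000023868). Its level was 774 CPM (761 to 786) in scrambled tumour nuclei, 656 CPM (638 to 675) with shPde10a-1 and 695 CPM (682 to 709) with shPde10a-4. The ratios to scrambled were 0.85 (0.82 to 0.88) and 0.90 (0.88 to 0.92). Host cells did not share this order. In excitatory neuron-like nuclei Pde10a was at 795 CPM in scrambled, 911 with shPde10a-1 and 950 with shPde10a-4, and in striatal projection neuron-like nuclei, its main site in the brain, at 3887, 3977 and 4129 CPM. The latter class had only 9 scrambled nuclei, and its name rests on a bound loosened after the clusters were seen. Over all nuclei, where neurons took a larger part of the hairpin libraries, the ratios were 1.28 and 1.04. The counts do not separate nuclear precursor RNA from mature RNA. Tumour clusters, taken over all libraries, also differed in Pde10a. Clusters 3 and 5, both mostly shPde10a-1 nuclei, were at 513 and 883 CPM. Clusters 0 and 2, mostly scrambled, were at 750 and 776 CPM, and cluster 1, mostly shPde10a-4, at 771 CPM. The library ratios therefore also reflect the mix of clusters and need not hold within each.

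**Figure D1:**
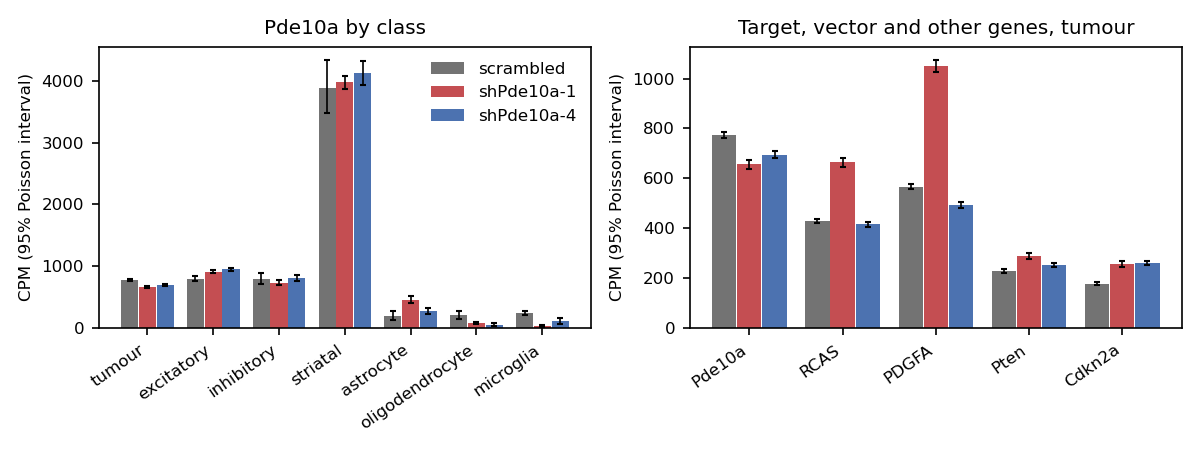
Bars give CPM of summed UMIs per library with exact 95% Poisson intervals, for Pde10a by class (left) and for Pde10a, 2 added vector features, Pten and Cdkn2a in tumour nuclei (right). Pde10a stood at 774, 656 and 695 CPM in tumour nuclei of the scrambled, shPde10a-1 and shPde10a-4 libraries, far below the striatal projection neuron-like nuclei.

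Vector transcripts marked the tumour compartment in every library. The RCAS feature was at 428 CPM in scrambled tumour nuclei, 664 with shPde10a-1 and 415 with shPde10a-4, against 39.7, 19.6 and 17.1 CPM in excitatory neuron-like nuclei. A RCAS UMI was seen in 74.2%, 67.0% and 61.6% of tumour nuclei (median 4090, 2967 and 3387 UMIs) and in 37.4%, 15.6% and 15.8% of excitatory neuron-like nuclei (median 12076, 9235 and 10309 UMIs), which give the background from free RNA. The PDGFA feature followed the same order, at 566, 1049 and 493 CPM. The red fluorescent marker of the hairpin vectors did not: mRFP had 68 UMIs in scrambled tumour nuclei, 4 with shPde10a-1 and 1 with shPde10a-4. Whether the reference sequence used matches the marker of every vector was not given in the sources used here. Per 1000 RCAS UMIs mRFP was at 8.32, 0.809 and 0.167. Pten, the phosphatase that opposes PI3K, was at 228, 286 and 250 CPM; whether its floxed allele was recombined was not given in the sources used here.

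Tumour nuclei made up less of the hairpin libraries and neurons more. The tumour compartment held 3906 of 4512 nuclei, or 86.6% (85.5 to 87.5), in the scrambled library, 52.0% (50.4 to 53.5) with shPde10a-1 and 72.7% (71.4 to 73.9) with shPde10a-4. Excitatory neuron-like nuclei made up 3.08%, 14.1% and 9.68%, inhibitory neuron-like nuclei 0.709%, 6.65% and 2.69%, and striatal projection neuron-like nuclei 0.199%, 4.61% and 0.812%. Oligodendrocyte-like nuclei took 1.31%, 7.54% and 3.44%, and astrocyte-like nuclei 0.842%, 4.42% and 2.47%. Microglia-like nuclei took 2.48%, 3.19% and 1.39%, endothelial-like nuclei 0.953%, 1.28% and 1.66%, and fibroblast-like nuclei 0.377%, 1.14% and 1.02%. Macrophage or monocyte-like nuclei (0.155%, 0.946% and 0.155%), whose name rests on the loosened bound, and mural-like nuclei (0.244%, 0.402% and 0.367%) were rare. Of the oligodendrocyte-like nuclei, 22, 121 and 31 lay in cluster 22, where PDGFA was at 713 CPM against 117 in cluster 7, so these may be tumour nuclei rather than host ones. The mural-like cluster 29 had RCAS at 443 and PDGFA at 401 CPM, so some of its nuclei may be tumour nuclei too. Tumours were cut out by eye, so the amount of adjoining brain in a piece can set these shares.

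**Figure D2:**
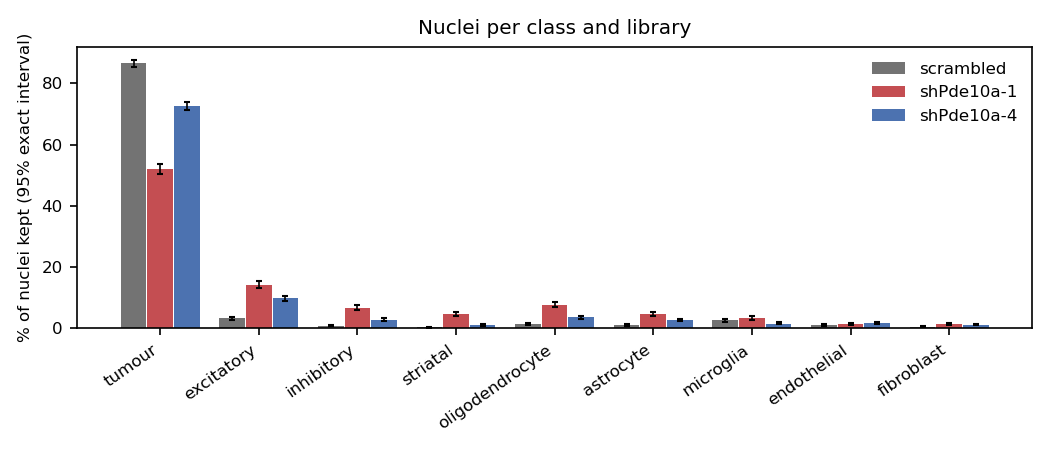
Bars give the percent of nuclei kept per library in the tumour compartment and in 8 other classes, with exact 95% Clopper-Pearson intervals. The tumour compartment held 86.6%, 52.0% and 72.7% of nuclei, and all neuron classes were larger in the hairpin libraries.

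The tumour compartment was OPC-like for the most part, at 72.2%, 40.6% and 61.2% of all nuclei, with proliferating progenitor-like nuclei at 14.4%, 11.3% and 11.5%. Of the tumour compartment alone the latter made up 16.6% (15.4 to 17.8), 21.8% (20.1 to 23.6) and 15.8% (14.7 to 17.1). Within it the libraries filled the clusters unevenly. Cluster 0, the largest, held 2064 scrambled, 90 shPde10a-1 and 1084 shPde10a-4 nuclei, and cluster 4 held 452, 104 and 386. Cluster 2 held 955 scrambled nuclei and cluster 1 held 1502 of the shPde10a-4 nuclei. Clusters 3 and 5 held 887 and 568 of the shPde10a-1 nuclei, against 13 and 11 scrambled nuclei, so some clusters here may be a library rather than a cell state. The unnamed shallow cluster 12 held 0.997%, 3.57% and 1.93% of nuclei and the unnamed shallow cluster 19 held 2.08%, 0.142% and 1.68%.

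Hairpin tumour nuclei shared a small set of genes that differed from scrambled in both libraries. Among 7618 genes of at least 20 CPM, 53 were at least 2-fold higher and 15 at least 2-fold lower in both. Both ratios were taken to the same scrambled library, so anything peculiar to that pool of mice enters both lists. Ranked by the smaller ratio, the first was Moxd1, a copper monooxygenase relative, followed by Vit, an extracellular matrix protein gene, and Hmga2, a chromatin factor of embryonic tissue and many tumours. Moxd1 (chromosome 10, 24223517 to 24302790) was at 1.83 CPM in scrambled, 98.6 with shPde10a-1 and 24.8 with shPde10a-4. Hmga2 (chromosome 10, 120361275 to 120476469) was at 20.5 CPM (18.5 to 22.6), 503 CPM (487 to 520) and 110 CPM (104 to 115), ratios of 24.6 (22.2 to 27.4) and 5.37 (4.80 to 6.01). Vit was at 2.15, 28.3 and 15.6 CPM, ratios of 13.2 and 7.27. All 3 genes were also leading genes of cluster 5, which was nearly absent from the scrambled library.

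The other named genes that were higher fell into neuron genes and genes of several other functions. Cck, Nrgn and Sv2c, which neurons use for a peptide, calmodulin binding and synaptic vesicles, were 6.50-, 5.35- and 4.80-fold higher with shPde10a-1 and 5.10-, 3.46- and 2.84-fold higher with shPde10a-4. These 3 were highest in neuron-like classes, and summed neuron markers in tumour nuclei were at 29.1 CPM in scrambled, 159 with shPde10a-1 and 97.4 with shPde10a-4. The mitochondrial protein gene Chchd10 was 6.99- and 3.93-fold higher, the lipid flippase gene Atp10b 6.56- and 3.69-fold, Iqcj 3.09- and 7.61-fold, and the urea transporter gene Slc14a1 4.60- and 2.28-fold. Eda2r, a p53-induced receptor gene, was 4.08- and 2.31-fold higher, and Fth1, the ferritin heavy chain gene, went from 71.9 CPM to 225 and 163. The sex of the mice differed as well: a Y-linked UMI was seen in 79.3% of scrambled nuclei, 0.0946% of shPde10a-1 nuclei and 62.7% of shPde10a-4 nuclei. Of the 53 genes, 29 were left unnamed because another class held over 10 times more of them and 3 because of their names or chromosome.

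The 15 genes that were lower included ion channels and transcription factors. Rtl4, a retrotransposon-derived gene (chromosome X, 144688907 to 145122411), went from 256 CPM (249 to 263) in scrambled to 40.1 (35.7 to 44.9) with shPde10a-1 and 103 (97.7 to 108) with shPde10a-4. Its neighbour Trpc5, a cation channel gene, had ratios of 0.233 and 0.432, and the potassium channel gene Kcnq4 had 0.195 and 0.425. Among transcription factor genes Maf had ratios of 0.305 and 0.424 and Mkx had 0.399 and 0.465. Prr16 was at 177 CPM, 58.0 and 66.0. Casp12 had ratios of 0.166 and 0.301, Cnn2 0.189 and 0.312, Cldn34c1 0.373 and 0.279, Skap2 0.445 and 0.447, Ifitm10 0.343 and 0.448, and Mydgf 0.457 and 0.399. Over all nuclei Mkx (shPde10a-1) and Trpc5 (both hairpins) were higher than in scrambled.

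**Figure D3:**
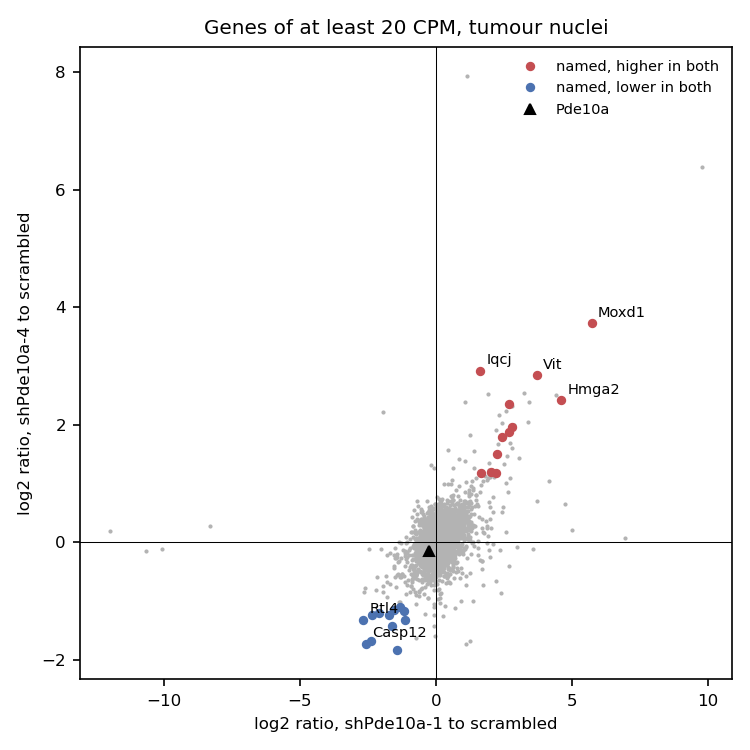
Each point is a gene of at least 20 CPM in tumour nuclei, with its log2 ratio to scrambled in the shPde10a-1 library (x) and the shPde10a-4 library (y). Red and blue points are the named genes that were at least 2-fold higher or lower in both, and the triangle is Pde10a, near the centre.

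The ratios of both hairpin libraries were correlated across genes, and both were taken to the same scrambled library. Pearson's r across the 7618 genes was 0.465, against 0.345 in 100 simulations of unchanged libraries, and the covariance was 0.0744 against 0.00251. The same-sign share was 61.5% against 61.2% in the simulations. The simulations held counting error only, so anything else peculiar to the scrambled pool could also raise r and the covariance. Genes are not independent replicates, and the single control library could not be split. The median gene stood at 0.10 with shPde10a-1 and 0.04 with shPde10a-4 on the log2 scale, and TMM scaling shifted it by -0.16 and -0.07, so list medians are best read against that shift.

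Hypoxia genes were among the highest of the 30 lists in both hairpin libraries, and mesenchymal genes were high as well. The hypoxia list had a median log2 ratio of 0.97 with shPde10a-1 and 0.90 with shPde10a-4, each at percentile 100, and 9 of 14 measured members were at least 1.5-fold higher in both. Vegfa, the main vessel growth factor, went from 47.6 CPM to 98.8 and 124. The glucose transporter gene Slc2a1 went from 3.98 to 8.45 and 12.6, and the hexokinase gene Hk2 from 1.36 to 6.44 and 7.07, though endothelial-like and microglia-like nuclei held over 10 times more of these 2. The mesenchymal list had medians of 0.89 and 0.53 (both percentile 100), with 7 of 17 members higher and 2 lower in both. Vim, an intermediate filament gene, went from 16.0 CPM to 55.7 and 35.2, Tnc, a matrix glycoprotein gene, from 37.2 to 87.5 and 66.6, and Runx2 from 77.5 down to 37.7 and 49.7. Endothelial-like nuclei held over 10 times more Vim. Without members that another class held over 10 times higher, the mesenchymal medians were 0.27 and -0.19 and the hypoxia medians 0.89 and 0.54.

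Glioma state lists moved less than these. The proneural list had medians of -0.18 (percentile 0.14) and 0.01 (percentile 48.2), with 0 of 18 members higher or lower in both. Its member Pdgfra was at 951, 850 and 1066 CPM, while Olig1 (228, 167 and 202 CPM), Cspg5 (1451, 903 and 1296 CPM) and Dcx (121, 75.8 and 98.1 CPM) were lowest with shPde10a-1. The classical list had 0.05 and 0.06 over 11 members (percentiles 21.2 and 49.4). The OPC-like state had 0.23 and -0.01 over 16 (percentiles 99.1 and 38.1), and the NPC-like state 0.20 and 0.21 over 13 (percentiles 80.7 and 99.0). The astrocyte-like state list had 0.36 and 0.38 (percentiles 99.8 and 100), with 5 of 12 members higher in both, among them Gfap (6.38, 36.5 and 16.2 CPM). All 5 were highest in astrocyte-like nuclei, which took a larger share of the hairpin libraries, and without members that another class held over 10 times higher the medians were 0.25 and 0.17. With TMM scaling the classical medians and the proneural median of shPde10a-4 turned negative.

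In RNA, components of the PI3K pathway, which the series title names, did not stand apart, and pathway activity itself was not measured. The PI3K-AKT-mTOR list had medians of 0.06 (percentile 49.8) and -0.03 (percentile 11.02), and 0 of 24 members passed 1.5-fold in both. Akt3 was at 732, 556 and 702 CPM and Pik3r1 at 413, 383 and 423 CPM. With TMM scaling both medians were negative. FOXO targets, which active AKT holds down, had medians of 0.13 and 0.08 over 16 members, near 0 with TMM scaling. The mTORC1 and SREBP target list was higher at 0.54 (percentile 100) and 0.17 (percentile 98.0), with 9 of 23 members higher with shPde10a-1 and 1 with shPde10a-4. Its sterol synthesis gene Hmgcr was at 87.0, 143 and 97.4 CPM and its amino acid transporter gene Slc7a5 at 35.3, 77.6 and 45.9 CPM.

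**Figure D4:**
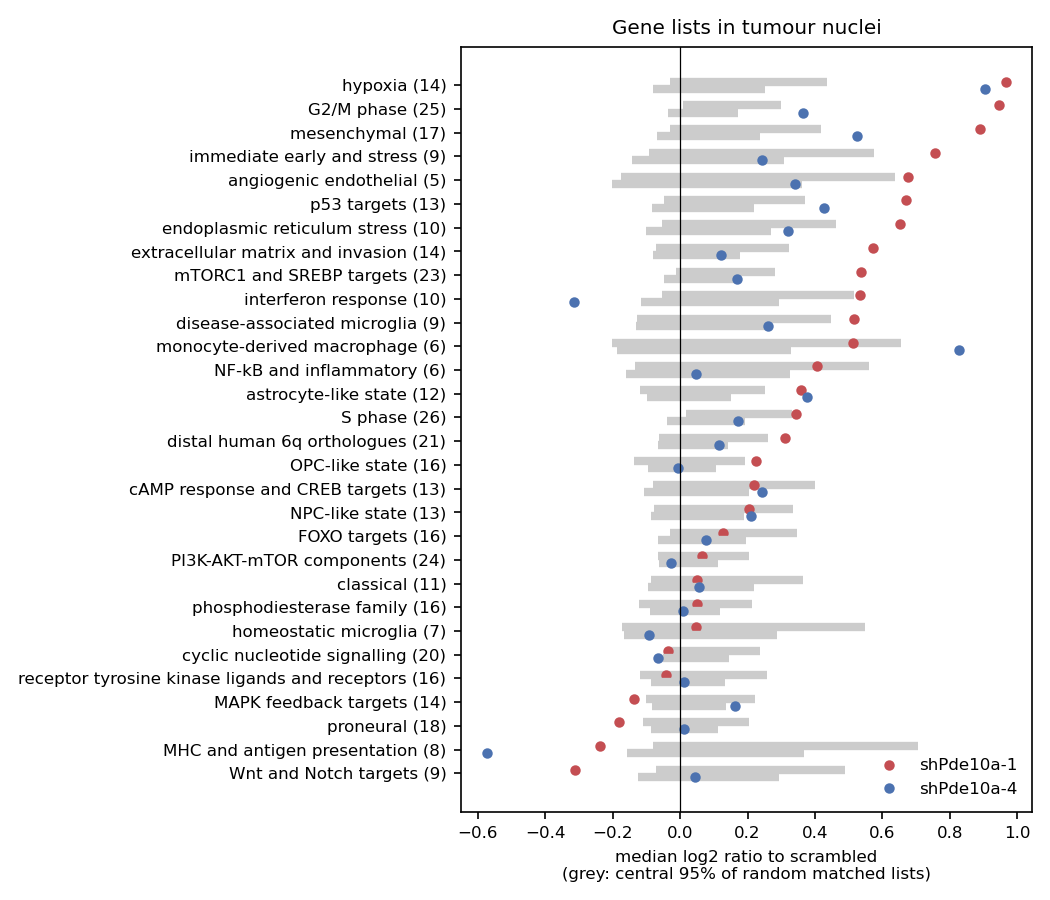
Points give the median log2 ratio to scrambled of each of 30 gene lists in tumour nuclei, in red for shPde10a-1 and blue for shPde10a-4, with the number of measured members in brackets. Grey bars span the central 95% of random lists matched on size and expression; hypoxia (0.97 and 0.90), G2/M (0.95 and 0.36) and mesenchymal (0.89 and 0.53) lay above them in both libraries.

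Lists of the enzyme family and its pathway had medians near 0, though the pathway list was low among random lists. Targets of cAMP had small positive medians. The cyclic nucleotide signalling list had medians of -0.04 (percentile 2.45) and -0.07 (percentile 1.26). Of its 20 members 0 were higher and 2 lower in both, among them Rapgef3, a cAMP-activated exchange factor gene (54.7, 19.9 and 32.2 CPM). The phosphodiesterase family had 0.05 and 0.01 over 16 members, both negative with TMM scaling. The abundant Pde4b was at 1823, 2013 and 2020 CPM and Pde4d at 1890, 1750 and 1855 CPM. The cAMP response and CREB target list had 0.22 (percentile 70.9) and 0.24 (percentile 99.2), with 4 of 13 members higher in both, such as Junb (6.54, 17.2 and 10.3 CPM). Of these, Junb, Vgf and Rgs2 were over 10 times higher in another class, and without such members the medians were 0.12 and 0.15. The receptor tyrosine kinase list had -0.04 and 0.01 over 16 members. The distal 6q orthologue list had 0.31 and 0.12 over 21 members, and its member Ermard was at 253, 1008 and 212 CPM.

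Stress, matrix and immune lists were mostly higher with shPde10a-1. The p53 target list had medians of 0.67 and 0.43 (both percentile 100), with 5 of 13 members higher in both, such as Cdkn1a (3.45, 20.9 and 7.00 CPM). Endoplasmic reticulum stress had 0.65 and 0.32 over 10 members, immediate early and stress genes 0.76 and 0.24 over 9, and extracellular matrix and invasion 0.57 and 0.12 over 14. NF-kB and inflammatory genes had 0.41 and 0.05 over 6, angiogenic endothelial genes 0.68 and 0.34 over 5, and Wnt and Notch targets -0.31 and 0.04 over 9. MHC and antigen presentation genes had negative medians in both, at -0.24 and -0.57 over 8. With TMM scaling the NF-kB, Wnt and Notch and receptor tyrosine kinase medians of shPde10a-4 and the homeostatic microglia median of shPde10a-1 turned negative. Microglial and macrophage lists, which mix free RNA with genes that tumour nuclei express, such as Vegfa, had 0.05 and -0.09 (homeostatic), 0.52 and 0.26 (disease-associated) and 0.51 and 0.83 (monocyte-derived).

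More tumour nuclei expressed division genes in the hairpin libraries once depth was equalised, although only shPde10a-1 had a larger share of proliferating progenitor-like nuclei. After thinning, 9.40% (8.49 to 10.4) of scrambled tumour nuclei, 18.1% (16.4 to 19.8) of shPde10a-1 nuclei and 11.9% (10.9 to 13.01) of shPde10a-4 nuclei had at least 2 G2/M genes, leaving out 54, 87 and 94 shallower nuclei. Unthinned, the shares were 20.6%, 25.0% and 19.6%, so the shPde10a-4 library was not above scrambled at median depths of 3387 and 4090 UMIs. In thinned excitatory neuron-like nuclei, which do not divide, the share was 1.44%, 1.17% and 0.201%. Summed G2/M genes were at 650 CPM (638 to 661), 1240 CPM (1215 to 1266) and 833 CPM (818 to 848), and S phase genes at 750, 954 and 840 CPM. The G2/M list had medians of 0.95 and 0.36 (both percentile 100), with 23 of 25 members at least 1.5-fold higher with shPde10a-1 and 3 with shPde10a-4. Mki67, a marker of cycling cells, was at 36.8, 90.7 and 46.7 CPM and Top2a, a topoisomerase gene, at 133, 265 and 166 CPM. The S phase list had 0.34 and 0.17 over 26 members, but -0.062 and -0.082 without the largest tumour cluster and -0.41 and -0.18 over all nuclei. Without the proliferating progenitor-like clusters the G2/M medians were 0.33 and -0.20.

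Between the hairpin libraries, shPde10a-1 tumour nuclei stood further apart. Of the genes of at least 20 CPM, 60 were at least 2-fold higher and 133 at least 2-fold lower with shPde10a-4 than with shPde10a-1, and 210 were higher and 75 lower in shPde10a-1 against scrambled, compared with 61 and 29 for shPde10a-4. Casq1, a calcium-binding protein gene of muscle, was at 0.471 CPM in scrambled, 1.07 with shPde10a-1 and 125 with shPde10a-4. The matrix genes Tnn (0.262, 36.8 and 0.277 CPM) and Cnmd (1.62, 52.6 and 1.87 CPM) were high with shPde10a-1 alone, as were Clca3a1 (22.0 against 1.25 CPM with shPde10a-4), Rasgef1c (30.7 against 2.36) and Ndst3 (292 against 30.4). Rit2 (13.8 CPM with shPde10a-1, 70.9 with shPde10a-4), Stk32b (5.37 and 20.1), Adcy8 (6.04 and 21.6) and Scn7a (10.5 and 36.1) were lower with shPde10a-1. Casq1 was among the leading genes of cluster 1, and Tnn and Cnmd were among those of cluster 3, clusters that were largely 1 library each.

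Excitatory neuron-like nuclei, the only host class with at least 100 nuclei in every library (139, 597 and 501), also differed between libraries. Of 7523 genes, 17 were at least 2-fold higher and 39 at least 2-fold lower in both hairpin libraries. The make-up of the class differed too, with 18, 3 and 60 nuclei in cluster 27 and 26, 213 and 101 in cluster 9, so a different mix of neuron types may enter these ratios. The correlation of ratios was 0.593 against 0.769 simulated for unchanged libraries with as few scrambled nuclei. Ldlr, the low-density lipoprotein receptor gene, was at 2.75 CPM (0.894 to 6.43) in scrambled, 35.4 with shPde10a-1 and 17.7 with shPde10a-4, and Tll1 at 11.02, 153 and 59.4 CPM. C77080 (6.61, 34.5 and 23.4 CPM), Col5a3 (1.65, 20.4 and 5.59) and the stress gene Gadd45b (4.41, 29.4 and 12.1) were higher too. Adamts2 was lower at 71.6, 11.3 and 27.1 CPM, as were Vwc2l (165, 69.6 and 73.3), Stard5 (46.3, 12.8 and 20.6), Npr2 (28.1, 13.3 and 12.2) and Rmdn2 (22.0, 8.97 and 8.57). The hypoxia list was higher here too, at 0.48 (percentile 99.9) and 0.23 (percentile 98.9) over 11 members.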

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

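The tests of Pde10a, of host RNA and of the hypoxic cluster, and the choice of lists compared between the hairpins, were made or revised after the results were seen, while those of sex, of a shift of all nuclei and of depth were written before. The spread required in the tests of sex and of a shift of all nuclei was added after their values were seen, and as single values both had passed the bounds first set against these explanations.

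Over all tumour clusters together, Pde10a was only slightly lower in hairpin tumour nuclei, at 0.85 and 0.90 of the scrambled level. Free RNA from striatal neurons did not account for this, since the lower ratio was still 0.764 when every striatal marker UMI in tumour nuclei was taken as free RNA and its Pde10a subtracted (455 against 595 CPM). A candidate explanation is that the hairpin vector was rare or silent in these nuclei, although red cells had been sorted after transduction. The mRFP level per RCAS UMI was 0.0972 and 0.0201 of the scrambled value, with the highest upper bound at 0.261. However, the RCAS feature does not say which vector it came from. Whether the mRFP reference sequence matches the marker of the hairpin vectors is not known. Nuclear RNA that the hairpins do not reach stays open too, because only nuclear RNA was measured, with a ratio of 0.899 for shPde10a-4. A weak effect of the hairpins themselves was not tested.

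The hypoxia and mesenchymal lists were higher in both hairpin libraries, and no technical explanation tested was excluded. Host nuclei of the same library held a median of 0.993 times (0.766 to 1.85) the tumour level of hypoxia members with shPde10a-4 and 1.14 times (0.851 to 1.80) with shPde10a-1. For mesenchymal members the hairpin value nearest to 1 was 1.45 times (0.794 to 2.67). Host RNA at a level near 1 would leave the median hypoxia member about unchanged. All these intervals reached above 1, so a part from free RNA was not excluded for either list. For the mesenchymal list of shPde10a-4 the direction itself was open: the median was 0.63 with free RNA subtracted but -0.19 without members prone to free RNA. Without the cluster led by Vegfa and Adm the lowest part of a list median left was 0.565 (the hypoxia list of shPde10a-4), and with members chosen again that median was 0.37 and the mesenchymal one 0.18. For sex of the mice, 0.935 of the hypoxia and 1.28 of the mesenchymal median of shPde10a-4 were left among nuclei with a Y-linked UMI. Most of either median thus remained in male-like shPde10a-4 nuclei. For shPde10a-1 sex cannot be told apart from an effect of the hairpin. For a shift of all nuclei of a library, hypoxia medians in excitatory neuron-like nuclei were at most 0.497 of those in tumour nuclei. Both results differed from bounds set at 0.5 by less than the spread of the members, so neither explanation was excluded. An effect of lower Pde10a on these genes is a hypothesis that 1 library per condition could not test.

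More tumour nuclei expressed division genes in the hairpin libraries after thinning, although proliferating progenitor-like nuclei took 16.6%, 21.8% and 15.8% of the tumour compartment, which was no higher with shPde10a-4. The test of depth of the nuclei could not decide, because the pattern was itself stated at equal depth. There the lower hairpin share was 11.9% (10.9 to 13.01) against 9.40% (8.49 to 10.4) in scrambled, which met the bound set against depth. With 1 G2/M gene the share was also higher with shPde10a-4, at 27.8% (26.4 to 29.3) against 25.1% (23.7 to 26.5) in scrambled, with intervals that overlapped slightly. Sex of the mice stays open by the bound set, which asked for intervals that do not overlap. Among nuclei with a Y-linked UMI the share was still higher with shPde10a-4, at 11.3% (10.1 to 12.6) against 9.18% (8.20 to 10.2) in scrambled. These intervals overlapped, but overlap alone does not show that the shares were equal. The shPde10a-1 library had 2 such nuclei. An effect of the hairpins, a difference between the pooled mice and a different part of the tumour being sampled may each account for the pattern, and the design does not separate them.

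The interferon response list was higher with shPde10a-1 and lower with shPde10a-4, with medians of 0.53 (percentile 98.0) and -0.31 (percentile 0.03) over 10 members, and the difference was not tested. Its members Oasl2 (5.86, 18.1 and 2.64 CPM) and Usp18 (4.55, 11.3 and 2.22 CPM) went the same ways, and cluster 25, led by interferon genes, held 77, 14 and 6 nuclei. Ddx60, an interferon-induced helicase gene (chromosome 8, 61928087 to 62038244), went opposite ways at 16.0, 38.2 and 4.99 CPM, log2 ratios of 1.26 and -1.67, a difference that was not tested. The MAPK feedback list also differed in sign, with medians of -0.14 (percentile 0.73) and 0.16 (percentile 99.2) over 14 members and no test of the difference, while its members Etv5 (176, 98.5 and 133 CPM) and Ccnd1 (331, 227 and 283 CPM) were below scrambled in both. The PDGFA feature was at 1118 CPM in unnamed cluster 12 and at 522 CPM in unnamed cluster 19, both outside the tumour compartment unless clusters were defined by PDGFA, against at most 40.8 CPM in excitatory neuron-like nuclei.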

How the results depend on the processing

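Added after the data were seen were the settings that defined tumour clusters by PDGFA, subtracted free RNA, kept only nuclei with a Y-linked UMI, left out the hypoxic cluster, or left out list members prone to free RNA. Across all settings 232 values of the main results stayed within their counting or member interval, 53 moved and 5 reversed. Not every change of sign was counted as reversed. The proneural and mesenchymal medians of shPde10a-4 and the PI3K-AKT-mTOR median of shPde10a-1 turned negative in some settings without entering the 5 reversals. Before any change of setting, their member intervals held both negative and positive values. Of values of named genes 606 stayed, 87 moved and 3 reversed, and of the other lists 811 stayed, 28 moved and 4 reversed. No paired analysis was possible because each condition had 1 library and the conditions share only 1 replicate number. The cause of the shifts below was not tested unless stated, and values are for shPde10a-1, then shPde10a-4, unless named.

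With all nuclei in place of the tumour compartment, the Pde10a ratios reversed to 1.28 and 1.04, the G2/M medians to -0.032 and -0.044, the S phase medians to -0.41 and -0.18, Trpc5 to log2 ratios of 0.52 and 0.51 and Mkx to 0.13 with shPde10a-1. There the proneural medians were -0.66 and -0.27, the PI3K-AKT-mTOR median of shPde10a-4 was -0.071, r was 0.806 and 407 genes were higher in both. This setting mixes in the host nuclei that differ in share. With TMM scaling the Pde10a ratios were 0.761 and 0.855, the PI3K-AKT-mTOR medians -0.093 and -0.099, and the G2/M median of shPde10a-1 was 0.79. Averaging over nuclei gave G2/M medians of 0.76 and 0.19. Without the proliferating progenitor-like clusters they were 0.33 and -0.20, a reversal for shPde10a-4. Without the largest tumour cluster they were 0.35 and 0.12, the S phase medians reversed to -0.062 and -0.082, the Pde10a ratio of shPde10a-4 was 0.949 and 25 genes were lower in both.

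The tumour share followed the clustering. In the order scrambled, shPde10a-1 and shPde10a-4 it was 89.5%, 55.7% and 76.7% with at least 1000 genes per nucleus, 88.8%, 55.7% and 76.2% at the lower resolution, and 90.4%, 58.9% and 77.3% with clusters defined by PDGFA. It was 87.7% in scrambled and 38.8% with shPde10a-1 at the higher resolution, and 38.5% with shPde10a-1 when doublets were kept. In these last settings 713 and 710 shPde10a-1 nuclei lay in unnamed clusters with PDGFA up to 1260 and 1241 CPM. There the values of shPde10a-1 were Pde10a ratios of 0.768 and 0.778, G2/M medians of 1.29 and 1.20, hypoxia medians of 1.12 and 1.11 and dividing shares of 23.1% and 22.0%. With clusters defined by PDGFA the Pde10a ratio of shPde10a-1 was 0.807.

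With free RNA subtracted the Pde10a ratios were 0.754 and 0.871, the G2/M median of shPde10a-1 was 1.10, r was 0.566 and 41 genes were lower in both. The hypoxia median of shPde10a-4 was 0.43 with members of at least 20 CPM and 0.37 without the hypoxic cluster. With no minimum CPM, 826 genes were higher and 680 lower in both, since genes of few UMIs then enter. Dividing shares in the order scrambled, shPde10a-1 and shPde10a-4 were 20.6%, 25.0% and 19.6% unthinned, where depth enters, and 25.1%, 34.3% and 27.8% with 1 G2/M gene. The mesenchymal median of shPde10a-4 was negative at -0.07 with members of at least 20 CPM and at -0.19 without members prone to free RNA, within its member interval of -0.25 to 1.01.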

Other observations

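All values in this part were looked at after the data were seen, except the excitatory neuron-like lists, which were planned. Microglia-like nuclei, fewer than the planned minimum at 112, 135 and 72, held more homeostatic transcripts per UMI in the hairpin libraries, largely along with less tumour RNA. The homeostatic list had medians of 0.81 and 0.96 (both percentile 100), with 9 of 12 members at least 1.5-fold higher in both, such as Cx3cr1 (673, 1027 and 1019 CPM), P2ry12 (460, 712 and 903 CPM) and Tmem119 (33.5, 137 and 110 CPM). Over 9 abundant OPC-like genes, these nuclei held a median of 42.3%, 7.94% and 14.9% of the tumour level, as for Lhfpl3 at 4890, 675 and 1733 CPM. With that part of the UMIs taken out, the homeostatic medians were 0.14 and 0.40. No such correction was made for the values that follow. The disease-associated list had medians of -0.20 and 0.10 over 15 members. Its members Lpl (386, 219 and 163 CPM) and Axl (125, 109 and 42.0 CPM) were below scrambled in both hairpin libraries, while Spp1 (43.5, 362 and 147 CPM) was above. The monocyte-derived macrophage list had 0.63 and 1.65.

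In excitatory neuron-like nuclei the lists of tumour-rich genes were lower in the hairpin libraries, with medians of -0.81 and -0.48 for the proneural list (both percentile 0) and -0.42 and -0.43 for the OPC-like state, in step with the RCAS feature (39.7, 19.6 and 17.1 CPM). Immediate early and stress genes had medians of -0.14 with shPde10a-1 and 0.78 (percentile 100) with shPde10a-4, and cAMP response and CREB targets 0.16 and 0.65. PI3K-AKT-mTOR components had -0.12 and -0.09 there.

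Sex-linked transcripts differed between the pools of mice. Gm26992, a gene model at the X-inactivation region (chromosome X, 103422010 to 103481705), was seen in 0.443% of scrambled nuclei, 79.8% of shPde10a-1 nuclei and 16.0% of shPde10a-4 nuclei, against 79.3%, 0.0946% and 62.7% for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. In excitatory neuron-like nuclei the shares were 0.719%, 84.8% and 49.9% for Gm26992 and 95.7%, 0.168% and 40.5% for the Y-linked genes. In tumour nuclei they were 0.384%, 85.2% and 11.03% for Gm26992 and 81.2%, 0.0910% and 69.7% for the Y-linked genes. Sex therefore runs together with the hairpin for shPde10a-1, while most shPde10a-4 tumour nuclei were male-like, as in scrambled. Within shPde10a-4 tumour nuclei, the 2578 with a Y-linked UMI alone had Pde10a at 706 CPM and Hmga2 at 100.1 CPM, and the 373 with Gm26992 alone had 675 and 179 CPM.

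Cdkn2a, the locus that the labels describe as deleted, was seen at 178, 256 and 259 CPM in tumour nuclei against 12.1, 5.98 and 4.55 CPM in excitatory neuron-like nuclei. A count per gene does not tell which exons or introns were read, so it does not check the deletion.

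A group of neighbouring genes on chromosome 17 was higher in tumour nuclei of shPde10a-1 than of the other libraries. Ermard (15041208 to 15090044) was at 253, 1008 and 212 CPM, Gm3417 at 177, 514 and 166, 9030025P20Rik at 122, 473 and 112, Gm3448 at 90.4, 299 and 103, and Gm3435 at 11.4, 30.1 and 10.9. The flanking genes Phf10 and Fam120b had ratios of 1.48 and 0.926, and in excitatory neuron-like nuclei Ermard stood at 18.2, 21.4 and 17.3 CPM. Oligodendrocyte-like nuclei of all libraries together held Ermard at 580 CPM. These gene models overlap or lie side by side, and reads may be shared among them. Ermard, Gm3417 and 9030025P20Rik led cluster 3, which held 887 of the 2197 shPde10a-1 tumour nuclei. The difference may therefore belong to a part of those nuclei. Over 318 windows of 5 Mb with at least 10 genes, window medians in tumour nuclei ran from -0.23 to 0.39 with shPde10a-1 and from -0.16 to 0.32 with shPde10a-4.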
